A study of Mus musculus with 9 samples.

How the data were processed

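The samples are ribosome-bound RNA from the retinae of tamoxifen-induced Aldh1l1-Cre/ERT2; NuTRAP mice, pulled down with an antibody against GFP (the positive fraction), per the labels' protocols. Per the labels, 2 retinae were pooled for each library, and libraries were taken 72 h after crush of the optic nerve or from fellow eyes that had been left untreated or had a sham procedure. Groups were taken from the treatment label and pools from the animal numbers, giving 5 ONC and 4 Control libraries. The series text speaks of n = 5, and a control library of pool 913/986 was not analysed here. The replicates are pools of animals, and the fellow eyes of 4 pools give pairs.

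The deposited values were normalized, per the file headers, which do not name a scale. That the deposited values are log2 and relative to a baseline for each gene was read from the values: they lie on both sides of 0, and their most repeated values lie exactly 1 apart. The table has 14194 entries, counted as genes throughout, for 14193 symbols, since Rims1 stands at 2 places. The headers also state the filter: raw values between 5 and 298892.188 in 100% of the libraries of at least 1 of the 2 conditions. A total of 13555 genes passed it in both conditions and 639 in 1. The submitters' processing notes name the mouse build mm10 and DESeq without a version, and the headers name RefSeq gene models. The aligner and the counting tool are not given in the sources used here. The baseline was checked on the values: 13230 genes have exactly 1 control library at 0, always 1 of the middle pair of the 4, and 959 genes (6.76%) have none at 0 with 2 controls on each side. That pattern fits a median over 5 control libraries, of which 4 were used here, although 20% of genes would lack a 0 if the 5 were alike. The centring narrows the spread over genes within a control library and leaves the spread of a gene between libraries as it was.

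Such values hold no absolute level and no library total. Whole counts were looked for in the ratios between libraries of 3000 genes (counts up to 3000, relative tolerance 2e-06) and came out for 2.57% of them, so the depth of each library is unknown. In 25 genes 2 or more libraries share the same lowest value below 0, all of them genes that passed the filter in 1 condition, and folds of such genes depend on that floor. Symbols of 22 genes had been turned into dates by a spreadsheet and were looked up by Entrez ID in a GRCm38.p6 gene table, in which 14171 of the 14194 IDs were found. That table was used for names alone, and coordinates are those of the deposited table. No value column of the table was left unused, and it holds no fold changes or p-values of the submitters. No library duplicated another, since at most 0.0564% of values were equal in any 2 of them.

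Each gene was tested with limma 3.58.1 in R 4.3.3 on the values as they stand, with ONC against Control, an empirical Bayes variance trend, no block and no other covariate. P-values are two-sided and adjusted over all 14194 genes by the Benjamini-Hochberg method, with a threshold of 0.05. The trend follows the mean of values that carry no expression level. Since each gene is centred on the controls, that mean follows its ONC minus Control difference, so the trend is tied to the change under test. The fit without a trend is given beside the main count. Gene lists were tested with camera at a preset correlation between genes of 0.01 and again with an estimated one, and with fry, over 34 lists with at least 3 measured members. Counts within a list were adjusted over all genes and over the list alone. Some genes stand in several lists, so the lists are not independent of one another. The lists, the tests across genes and lists, the rule for named genes and the alternatives, other than those named as added, were chosen before the data were examined. Permutation tests are two-sided. The fit was tested on simulated data for the comparison of ONC with Control, with the spread of each of the 14194 genes taken from the deposited values and with 100 genes changed by 1 and 100 by 3 on the log2 scale. It called 66.4% of genes changed by 1 on the log2 scale and 94.8% of those changed by 3, with 0.0729% of unchanged genes called. The same simulated data fitted with the animal pool as a block and a trend gave 0% at both sizes, and with the block and no trend 40.4% and 91.6%. Both blocked fits have 3 residual degrees of freedom in place of 7, so the 0% goes with the block and the trend together. In 5 simulated runs the list that had been shifted was found each time, and 1 of 165 tests of other lists passed. The simulated genes were drawn independently of one another and without pool effects. These runs therefore do not show how often camera passes lists whose genes move together.

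Genes are named by 3 rules. The first takes the 8 genes with the largest difference in each direction among those past the threshold with the same direction in all 4 pools. It was to require a level at or above the median of all genes, which these values cannot give, so that condition was dropped. The next takes 24 genes of Müller glia and their response, 23 of which were measured and 1 of these is not reported here, and the last takes for each list described up to 4 members past the threshold, or the 2 with the smallest p where none passed. A gene outside these rules is said to have been picked out after its value was seen.

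Animal numbers pair the libraries because both eyes came from the same animals, per the labels. The check on the values gave correlations of the deviations from the group means, between the eyes of a pool, of 0.377 for 914/92, 0.178 for 938/88, -0.0642 for 976/978 and 0.45 for 981/982. The best match in another pool was lower for Control 938/88 (0.0788) and Control 981/982 (0.351). It was higher for Control 914/92 (0.409, with ONC 913/986) and Control 976/978 (0.0922, with ONC 914/92). The values therefore do not bear out the pairs of pools 914/92 and 976/978. The numbers that end the column names, 34 to 39 for Control and 42 to 46 for ONC, do not overlap. What they stand for is not stated, and any effect that goes with them cannot be told apart from crush. Alternatives tried were the animal pool as a block, each library left out, quantile normalization, centring on the library median, limma without a trend or with robust weights and other thresholds. Added after seeing the data were fits without libraries of unusual Y-linked level, without both libraries of pool 914/92 (also with the block), with the block and no trend, fits with the Y-linked level or the level of rod, bipolar and amacrine markers as a covariate, a fit of genes that passed the filter in both conditions, and the gene lists under quantile normalization, centring and no trend.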

Results

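Ribosome-bound RNA was measured in mice 72 h after crush of the optic nerve. The fraction used was meant to hold RNA of Müller glia, the radial glia that span the neural retina. The mice carried a tamoxifen-inducible Cre driven by the astroglial gene Aldh1l1 together with NuTRAP, a reporter whose tagged ribosomes are pulled down with an antibody against GFP, and all libraries here come from that pulled-down fraction. In the crushed eyes (ONC) the nerve was clamped for 3 s about 1 mm behind the globe, and each library pooled 2 retinae. There were 9 libraries, 5 of crushed eyes (pools 913/986, 914/92, 938/88, 976/978 and 981/982) and 4 of control fellow eyes (Control, the same pools without 913/986). Fellow eyes were untreated or sham-operated, and the labels do not say which eye had which. Values of 14194 gene entries (14193 symbols, with Rims1 at 2 places) are on the log2 scale, each gene relative to a median of control libraries, so a value of 0 is the usual control level of that gene. Neither absolute levels nor sequencing depth can be recovered from such values, so how firmly a value is known rests on the spread between libraries alone.

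At 72 h after the axons that leave the retina were crushed, ribosome-bound RNA of the glial fraction was compared with that of fellow eyes. Ecel1, Sox11, Gal and Prss12, which are best known from neurons, and Il1rn, which restrains inflammation, were among the genes that rose most. Ecel1, a membrane protease of neurons that responds to nerve injury, rose 24.2-fold, from -0.31 ± 0.60 (SD, n = 4) in Control to 4.29 ± 0.45 (SD, n = 5) in ONC. Sox11, a transcription factor of developing neurons, rose 10.3-fold (log2 difference 3.36 ± 0.33 SE). Gal, the neuropeptide galanin, rose 12.9-fold, and Prss12, a synaptic serine protease, rose 15.8-fold. Il1rn, the antagonist of the interleukin-1 receptor, rose 14.9-fold and Cyp4f18, a cytochrome P450 that acts on leukotriene B4, rose 10.2-fold. Abcc3, an organic anion transporter, rose 10.1-fold, and Crabp2, a retinoic acid binding protein, rose 9.59-fold.

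The genes that fell most included Clstn2, Sncg, Vamp1 and Grin3a, which are known from neurons and their synapses. Clstn2, a postsynaptic adhesion protein, fell by 1.52 on the log2 scale, a 2.87-fold lower level. Sncg, the gamma-synuclein of retinal ganglion cells, was 2.51-fold lower, and Rbpms2, an RNA-binding protein of the same cells, was 2.23-fold lower. Vamp1, a vesicle protein of synaptic terminals, was 2.49-fold lower, Grin3a, an NMDA receptor subunit, 2.47-fold lower, and Kcnip4, a partner of voltage-gated potassium channels, 2.29-fold lower. Rimkla, which makes the neuronal dipeptide N-acetylaspartylglutamate, was 2.41-fold lower, and Vwa5b2 was 2.58-fold lower. In the coordinates of the deposited table, Ecel1 (gene ID 13599) lies on chromosome 1 from 87147655 to 87155027, Sox11 (20666) on chromosome 12 from 27334268 to 27342718, Clstn2 on chromosome 9 from 97444395 to 98033167 and Sncg on chromosome 14 from 34370274 to 34374669, on mm10.

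**Figure D1:**
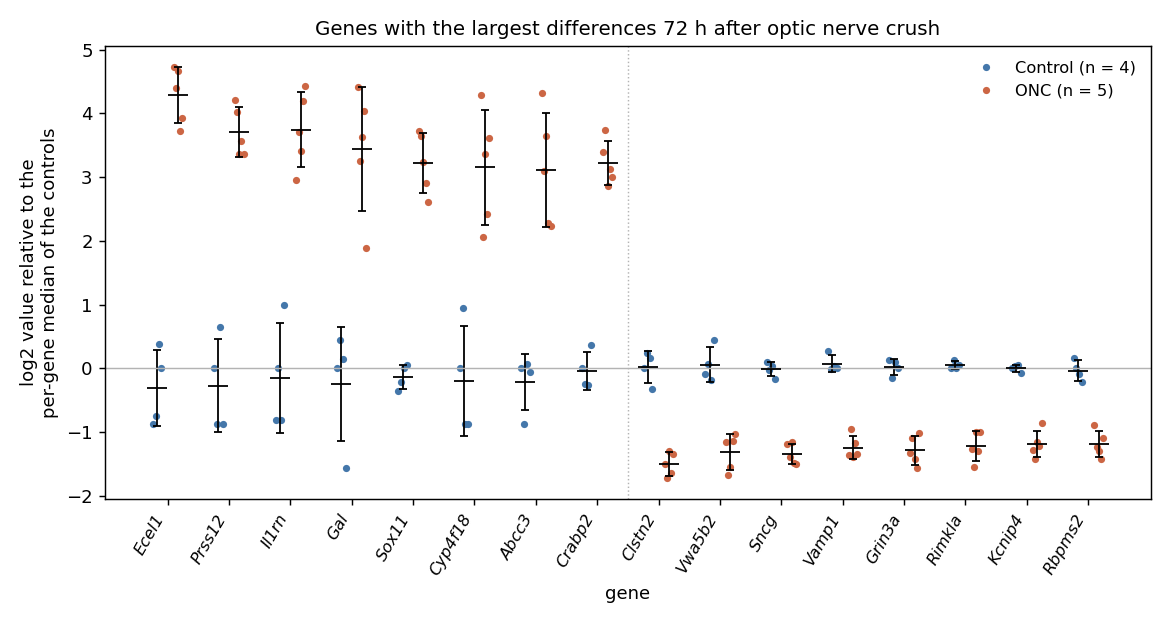
Log2 values relative to the per-gene median of the controls (y axis) for the 8 genes with the largest rise and the 8 with the largest fall after crush (x axis). Points are libraries, bars the mean ± SD of 4 Control and 5 ONC libraries; in each of the 16 genes every ONC library lies outside the range of the controls, with Ecel1 at 4.29 on average in ONC.

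In all, 50 of the 14194 genes changed at an adjusted p under 0.05 (limma with a variance trend, two-sided, Benjamini-Hochberg), 27 higher and 23 lower. The smallest adjusted p was 0.0119, for Sox11, Crabp2 and the predicted gene Gm13889, and 37 of the 50 had an adjusted p above 0.04. Each of the 50 moved the same way in all 4 pools that have both eyes, with every ONC library outside the range of the controls. Over all genes, 1111 (7.83%) showed no overlap between the groups, against 1.59% by chance. In 10 of the 50, all of them higher in ONC, the submitters' raw-value filter was passed in 1 of the 2 conditions alone. Among these, Il1rn, Prss12, Cyp4f18 and Slpi each have 2 control libraries at one shared lowest value, so their folds depend on that floor. The value of Abcc3 in Control 938/88, -0.868, equals the lowest value of Prss12 and Cyp4f18, so its fold may depend on the floor too. With the animal pool as a block limma called 0 genes (3574 at an unadjusted p under 0.05), the adjusted p of the 50 then lying between 0.0801 and 0.0939, whereas without a variance trend it called 165 genes that include all 50, and 129 with the block and no trend. Leaving out 1 library left 0 calls without Control 938/88 or Control 976/978 (1954 and 1804 at an unadjusted p under 0.05), 3 without ONC 938/88, 4 without ONC 913/986, 6 without ONC 976/978, 8 without Control 981/982 and 26 without Control 914/92, with 15 genes lower without ONC 914/92 and 36 lower without ONC 981/982.

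Genes of reactive gliosis were higher after crush, whereas the list of genes by which Müller glia serve the retina at rest had a small median difference. Camera placed the gliosis list above other genes (median 1.08, adjusted p = 3.5e-07, and adjusted p = 0.232 with an estimated correlation). Of 15 measured pan-reactive genes, 11 were higher when adjusted over the list alone, and 1, Serpina3n, an acute-phase protease inhibitor, also over all genes (4.81-fold, adjusted p = 0.0497). Gfap, the intermediate filament of reactive glia, had a log2 difference of 1.80 ± 0.56 (SE), a 3.48-fold higher level, and Vim, another intermediate filament, one of 0.99, but over all genes their adjusted p were 0.153 and 0.132. Lcn2, Timp1 and Osmr differed by 3.96, 3.07 and 1.18 on the log2 scale (adjusted p over all genes 0.160, 0.160 and 0.122), and Cp by 0.36 (adjusted p = 0.294). Control 914/92 stood toward the crushed eyes here: its median over the list was 0.83, against -0.18 to 0.00 in the other 3 controls, and its Gfap value was 1.92. The lists of A1-type and A2-type reactive genes were also higher, by medians of 0.78 and 0.79, with 5 of 11 and 5 of 9 members higher when adjusted over the list alone. Their adjusted p by camera were 1.8e-04 and 9.8e-05, and each had an adjusted p = 0.232 with an estimated correlation. Cd14, a co-receptor of Toll-like receptor 4, was 3.36-fold higher (adjusted p = 0.0191). Control 914/92 had medians of 0.89 in the A1 list (other controls -0.30 to 0.00) and 0.45 in the A2 list (-0.22 to 0.12). Markers of microglia and of other leukocytes rose beside these 2 lists and the gliosis list, by medians of 1.49 and 2.07.

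Glul, Rlbp1, Aqp4, Kcnj10 and Slc1a3, which recycle glutamate and retinoid and buffer water and potassium, differed by -0.26, -0.05, 0.01, 0.06 and 0.05 on the log2 scale, and none passed. Apoe and Sox9 differed by 0.21 and 0.41, and neither passed. As a list of 28, the homeostatic genes stood slightly above other genes (median 0.16, camera adjusted p = 0.0240, and adjusted p = 0.595 with an estimated correlation), but no member passed. The 2 smallest p belonged to Clu and Crym, with log2 differences of 0.61 and 1.22 (adjusted p over all genes 0.114 for both). Each was higher in 4 of 4 pools. With the animal pool as a block 6 members passed over the list alone. The call of the list ended without ONC 914/92 (adjusted p = 0.152) or Control 981/982 (0.325), without the 2 ONC libraries low in Y-linked RNA (0.579) and with Y-linked RNA (0.572) or neuron markers (0.699) as a covariate, in a range of 0.00234 to 0.699.

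Transcripts of genes of gp130 and STAT3 signalling, and of immediate early genes, were higher as lists after crush. Both lists passed camera (adjusted p = 2.3e-07 and 1.2e-08), each with an adjusted p = 0.232 with an estimated correlation. Of 22 measured genes of gp130 and STAT3 signalling, 11 were higher when adjusted over the list alone, and Bcl3, an atypical IκB protein, also over all genes (5.23-fold, adjusted p = 0.0497). Socs3, the feedback inhibitor of STAT3, differed by 2.09 and Stat3 itself by 0.81 on the log2 scale (adjusted p over all genes 0.0776 and 0.107). Of the ligands that act through gp130, Cntf differed by 1.37 (adjusted p = 0.102) and Lif by 1.03 (adjusted p = 0.294). Of 20 immediate early genes, 11 were higher when adjusted over the list alone and none over all genes. Atf3 and Junb had the smallest p of these, with log2 differences of 2.39 and 1.13 (adjusted p = 0.0626 and 0.0723). Cytokine and NF-kB genes passed too, with 8 of 19 higher over the list alone (13 with the animal pool as a block) and none over all genes (median 0.57, adjusted p = 7.1e-07, and adjusted p = 0.232 with an estimated correlation). Il1b and Tnfrsf12a had the smallest p of that list, with log2 differences of 3.26 and 2.19 (adjusted p = 0.0730 and 0.0746). Ccl2 was not among the genes measured. Microglia and leukocyte markers were higher beside these lists, by medians of 1.49 and 2.07. Control 914/92 stood toward the crushed eyes in all 3, with medians of 0.46 for gp130 and STAT3 (other controls -0.07 to 0.00), 0.40 for immediate early genes (-0.11 to 0.00) and 0.51 for cytokines (-0.03 to 0.00).

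Markers of microglia and of other leukocytes were higher as lists in the glial fraction of the crushed eyes. Their medians were 1.49 and 2.07, and both passed camera (adjusted p = 2.9e-07 and 1.4e-04, each with an adjusted p = 0.232 with an estimated correlation). Of 15 microglia and macrophage markers, 11 were higher when adjusted over the list alone (5 with the animal pool as a block), and Cd68, a lysosomal protein of phagocytes, also over all genes (8.64-fold, adjusted p = 0.0497). Of 6 markers of other leukocytes, 3 were higher over the list alone. The smallest p were those of S100a9 and Cd52, with log2 differences of 2.06 and 3.46 (adjusted p over all genes 0.0526 and 0.0575). Complement genes were also higher as a list, 10 of 15 being higher over the list alone (4 with the block) and none over all genes (median 1.43, adjusted p = 1.2e-05, and adjusted p = 0.232 with an estimated correlation). The complement and microglia lists were both fixed with C1qa, C1qb and C1qc, so their shifts are not independent. C4b and Serping1 differed by 1.82 and 1.56 on the log2 scale (adjusted p over all genes 0.0723 for both), and C3 by 2.96 ± 1.00 SE (adjusted p = 0.169). The microglia median was 0.28 in ONC 914/92 and 0.92 to 2.64 in the other 4 ONC libraries, and the complement median was likewise lowest there, at 0.28. Interferon and antigen presentation genes were higher as a list (median 0.74, adjusted p = 6.8e-08, and adjusted p = 0.390 with an estimated correlation), with 4 of 29 past the test over the list alone (16 with the block) and none over all genes, and with Ifitm3 and Tapbp at 1.53 and 0.51 (adjusted p = 0.0723 and 0.108). Control 914/92 had a median of 0.78 in this list, against -0.47 to 0.00 in the other 3 controls. ONC 938/88 and ONC 981/982, at 0.30 and 0.12, lay below Control 914/92. The interferon list did not pass by fry (adjusted p = 0.128).

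Genes of endoplasmic reticulum and integrated stress and of matrix, adhesion and cytoskeleton were higher as lists. Their medians were 0.23 and 0.55 (camera adjusted p = 2.4e-04 and 1.4e-05, each with an adjusted p = 0.232 with an estimated correlation). Of 20 stress genes, 4 were higher when adjusted over the list alone, among them Ddit3 (log2 difference 1.06, adjusted p over all genes 0.0526) and Chac1 (3.42, adjusted p = 0.0642). Of 27 antioxidant and metal handling genes, 6 were higher and 1, the transferrin receptor Tfrc, lower over the list alone, and Srxn1, which repairs oxidised peroxiredoxins, was higher over all genes (2.11-fold, adjusted p = 0.0282). The list's adjusted p was 2.5e-05 (adjusted p = 0.331 with an estimated correlation). Matrix, adhesion and cytoskeleton genes had 15 higher and 1 lower of 32 over the list alone. Plaur and Anxa2 had the smallest p of these, with log2 differences of 3.17 and 1.00 (adjusted p = 0.0575 and 0.0776). The lower one was Lamb1, a laminin chain. Tfrc and Lamb1 were picked out after their values were seen. Control 914/92 had medians of 0.20 in the matrix list (other controls -0.14 to 0.00) and 0.23 in the antioxidant list (-0.17 to 0.00). Its stress list median of 0.04 lay within the other controls (-0.04 to 0.09). Markers of microglia and of other leukocytes rose beside these lists, by medians of 1.49 and 2.07. Nuclear genes of oxidative phosphorylation showed a small shift (median 0.13 over 36 genes, adjusted p = 2.4e-04, and adjusted p = 0.331 with an estimated correlation), and no member passed, Sdhd and Sdhb having the smallest p.

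Smaller list shifts were those of heat shock (median 0.15, adjusted p = 0.0380), cell cycle (0.25, adjusted p = 0.0315), trophic factors (0.37, adjusted p = 0.0240) and, downward, cholesterol synthesis (-0.10, adjusted p = 0.0453). With an estimated correlation their values were adjusted p = 0.414, 0.311, 0.407 and 0.595, and over the list alone 3 of 14, 2 of 21, 2 of 24 (5 with the animal pool as a block) and 0 of 23 members passed. The heat shock genes Hspb1 and Bag3 differed by 1.04 and 0.83 (adjusted p over all genes 0.0766 and 0.0954), and the cell cycle genes Cdkn1a, an inhibitor of the cycle, and Rrm2 by 1.53 and 1.71 (0.0817 and 0.109). Among trophic factors Fgf1 was lower (-0.62, adjusted p = 0.0706) and Cntf higher over the list alone, while Fgf2 differed by 0.13 and Edn2 by 1.55 (0.825 and 0.208). Stard4 and Lss had the smallest p of cholesterol synthesis, with differences of -0.44 and -0.47 (adjusted p 0.132 for both). The call of cholesterol synthesis ended with the block (adjusted p = 0.140, 0.148 with the block and no trend, and 0.0526 with the block and without pool 914/92) and without Control 914/92 (0.206), Control 938/88 (0.0593), Control 976/978 (0.0953), ONC 913/986 (0.0970), ONC 938/88 (0.151) or ONC 981/982 (0.111). The heat shock call ended without Control 981/982 (adjusted p = 0.190), ONC 914/92 (0.0778), ONC 981/982 (0.0902) or the 2 ONC libraries low in Y-linked RNA (0.0719), with quantile normalization (0.108) and with Y-linked RNA as a covariate (0.0593). The cell cycle call ended without Control 938/88 (0.0593), Control 981/982 (0.0613) or those 2 ONC libraries (0.0854) and with Y-linked RNA (0.0847) or neuron markers (0.127) as a covariate. The trophic factor call ended without Control 938/88 (0.0504), Control 981/982 (0.0909) or those 2 ONC libraries (0.0814), with quantile normalization (0.0589) and with Y-linked RNA (0.0847) or neuron markers (0.149) as a covariate.

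Markers of retinal ganglion cells, whose axons were crushed, fell as a list in the glial fraction. The list's median difference was -0.82 (camera adjusted p = 1.4e-05, and adjusted p = 0.232 with an estimated correlation), and all 5 ONC libraries, from -1.21 to -0.53, lay below all 4 controls, from -0.24 to 0.11. Of 14 measured, 9 were lower when adjusted over the list alone, and Sncg also over all genes. One member went up over the list alone, Gap43, a growth cone protein of regrowing axons (log2 difference 1.05, picked out after its value was seen). Horizontal cell markers fell as a list (median -0.68, adjusted p = 0.00329, and adjusted p = 0.311 with an estimated correlation), with Calb1 and Onecut1 at -1.26 and -2.23 lower over the list alone (adjusted p over all genes 0.0782 and 0.160), and 4 of 5 members past with the animal pool as a block. Rod and bipolar markers fell by medians of 0.30 and 0.40 on the log2 scale (adjusted p = 0.0380 and 0.0229, each with an adjusted p = 0.595 with an estimated correlation), and no member of either passed. The rod call ended with quantile normalization (adjusted p = 0.213) and without Control 938/88 (0.0859), Control 976/978 (0.0758), Control 981/982 (0.162), ONC 913/986 (0.0954) or ONC 914/92 (0.345), and the list's direction turned without the 2 ONC libraries low in Y-linked RNA (0.592) and with the Y-linked level as a covariate (0.596), in a range of 0.00204 to 0.596. The bipolar call ended without Control 981/982 (0.135) or ONC 914/92 (0.105), without those 2 ONC libraries (0.374), with quantile normalization (0.0651) and with the Y-linked level as a covariate (0.372), in a range of 0.00148 to 0.374 that leaves out the covariate made of these markers. Rod medians ranged from -1.14 to 0.10 in ONC and from -0.65 to 0.16 in Control, the lowest being in both libraries of pool 914/92 and in ONC 913/986.

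The other lists did not pass camera, at adjusted p of 0.0763 for amacrine markers (median -0.27), 0.104 for cone markers (-0.43), 0.104 for glycolysis (-0.12), 0.104 for Notch, BMP, Wnt and reprogramming genes (0.14), 0.111 for crystallins (0.51), 0.161 for pigment epithelium (-0.30), 0.439 for the visual cycle (-0.02), 0.494 for transmitter and ion buffering (0.01), 0.708 for both endothelial (-0.10) and pericyte (-0.23) markers and 0.920 for retinal astrocytes (-0.01). Without Control 914/92 the lists of amacrine markers (adjusted p = 0.0221), cone markers (0.0367), glycolysis (0.0283), reprogramming genes (0.0283), crystallins (0.0326) and pigment epithelium (0.0283) passed, cone markers also without Control 938/88 (0.0321) or ONC 976/978 (0.0166), and amacrine markers without ONC 938/88 (0.0210) or ONC 981/982 (0.0208). Without both libraries of pool 914/92, amacrine markers (0.0474), glycolysis (0.0364), reprogramming genes (0.0125), crystallins (0.0329) and pigment epithelium (0.0329) passed. Without the 3 libraries low in Y-linked RNA, glycolysis (0.0402), reprogramming genes (0.0346), crystallins (0.0389) and pigment epithelium (0.0294) passed, as did the last 3 with the block and without pool 914/92 (0.0166, 0.0164 and 0.0160) and reprogramming genes with quantile normalization (0.0374). Sox11, a reprogramming list member, and Crabp2, a visual cycle list member, changed over all genes. The visual cycle list had a mean of 0.19 and an upward direction by camera, and the transmitter list a mean of -0.05 and a downward one, each opposite in sign to its median. Lens and blood markers had 2 measured members each and mitochondrially encoded genes 0, so these 3 lists were not tested. In all, 23 of 34 lists passed, 18 up and 5 down, and some of these share members. By camera, 0 lists passed with an estimated correlation (6 at an unadjusted p under 0.05), and 22 passed with the animal pool as a block, all of them among the 23. Tested without comparison with other genes, 14 lists moved mainly one way and 19 changed in either direction (fry, adjusted p under 0.05). Past camera but not past fry for 1 direction were homeostasis (fry adjusted p = 0.394), interferon (0.128), trophic factors (0.132), cholesterol synthesis (0.283) and heat shock (0.121). The same held for the antioxidant (0.0552), cell cycle (0.0552), rod (0.415) and bipolar (0.328) lists.

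**Figure D2:**
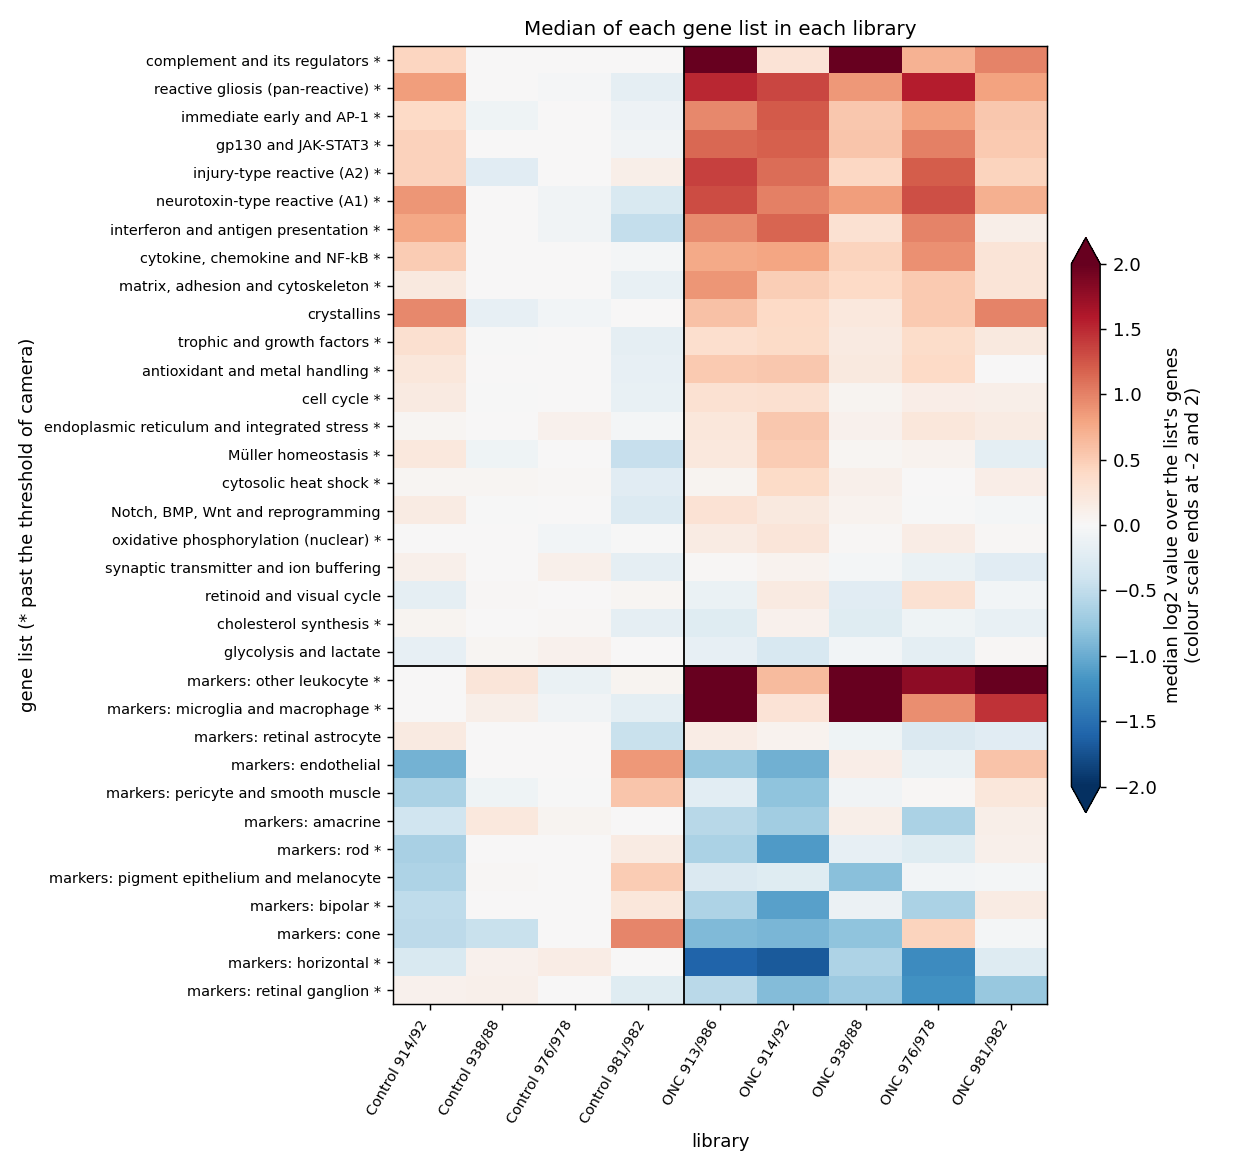
Median log2 value of each gene list (rows) in each library (columns), relative to the per-gene control median, with Control left and ONC right of the line. Asterisks mark the 23 lists past the threshold; Control 914/92 has a gliosis median of 0.83, and the microglia median of ONC 914/92, 0.28, is the lowest of the crushed eyes.

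Pearson correlations across genes, which are not independent replicates, had a median of 0.534 over the 10 pairs of ONC libraries and of -0.07 over the 6 pairs of controls. Values centred on the control median hold the correlations among controls near or below 0 and give those among ONC libraries the shared difference from control, so these values do not compare how alike the libraries of each group were. The spread of values over genes was 0.468 to 0.814 (SD) in ONC and 0.269 to 0.401 in Control, which the same centring narrows. The first principal component held 43.6% of the variance and the second 19.4%. Control 914/92 correlated with ONC 913/986 and ONC 914/92 at 0.489 and 0.492.

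The libraries also differed in RNA of the Y chromosome. The mean over Ddx3y, Uty, Kdm5d and Eif2s3y was -7.88 in ONC 913/986, -7.83 in ONC 914/92 and -1.22 in Control 914/92, and -0.03 to 0.51 in the remaining 6 libraries. The crushed and fellow eyes of pool 914/92 therefore differed by -6.61, against at most 0.311 in size within the other 3 pools. None of the 50 changed genes lies on the X or Y chromosome. That does not show whether the Y-linked difference enters the calls. Y-linked means spread from -7.88 to 0.20 within the ONC group, which leaves such genes little chance of being called. Without the 2 ONC libraries that had almost no Y-linked RNA limma called 0 genes at an adjusted p under 0.05 and 1571 at an unadjusted p under 0.05, the latter with all 50 genes, at a median of 0.953 times their log2 differences, while without both libraries of pool 914/92 it called 44, of which 41 were higher.

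**Figure D3:**
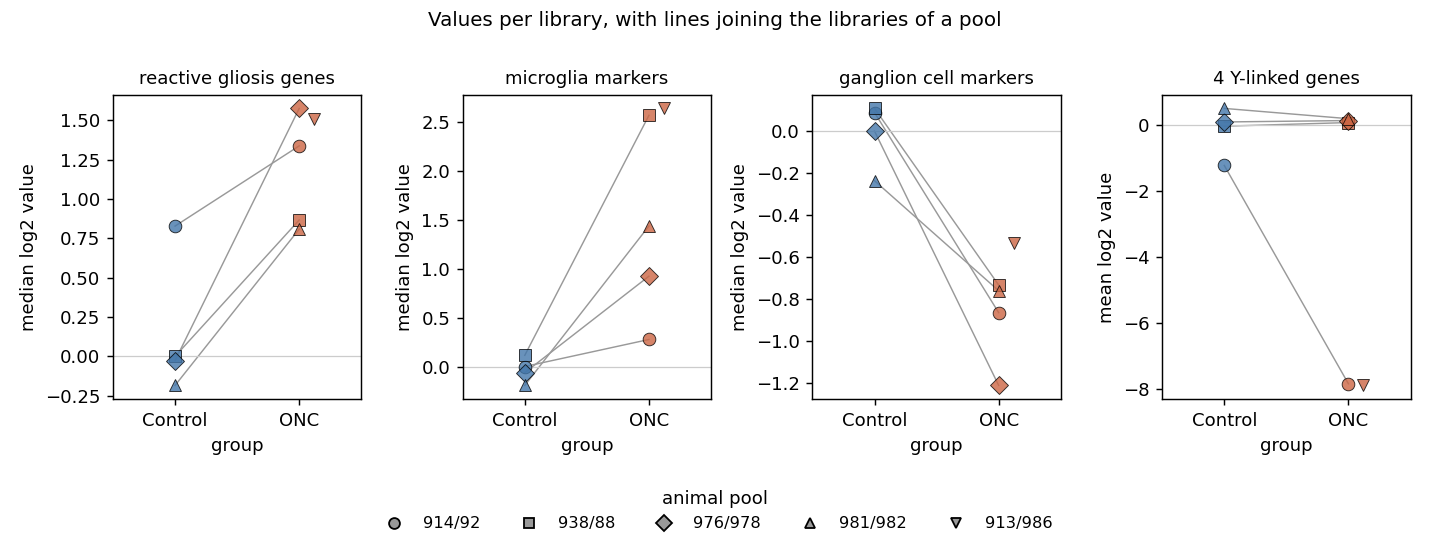
Values per library (y axis, log2 relative to the control median) for the medians of the reactive gliosis genes, microglia markers and ganglion cell markers and the mean of 4 Y-linked genes, in Control and ONC (x axis). Marker shapes are animal pools and lines join both libraries of a pool; the Y-linked mean of pool 914/92 goes from -1.22 to -7.83.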

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

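The tests of single libraries against their group and of other splits of the libraries were planned, and the other tests of explanations here were chosen after the results were seen. Among 262 groups of libraries, each a named gene or the median of a list in 1 group, 16 had 1 library far from the others by Dixon's criterion, where chance gives about 1 in 20, or 13.1; that rate was not tested for medians of lists whose members are each centred on the controls. Of these, 7 were in Control 914/92: Lif at 1.82, Vamp1 at 0.28, and the medians of gp130 and JAK-STAT3 genes at 0.46, complement at 0.43, cytokines at 0.51, crystallins at 0.97 and the visual cycle at -0.18. ONC 981/982 stood apart in Il1b (4.38, others at most 3.08), Pdk4 (-0.63, others at least 0.63) and the lens genes Bfsp1 (2.80) and Bfsp2 (0.71). ONC 914/92 stood apart in C3 (-0.86, other crushed eyes 3.30 to 4.68) and Onecut1 (-4.08). Control 981/982 stood apart in Kcnj10 (-0.56) and the heat shock median (-0.22), and Control 938/88 in Abcc3 (-0.87, equal to the lowest value of Prss12 and Cyp4f18).

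Control 914/92 shows reactive genes near the level of crushed eyes, as its median over the gliosis list, 0.83, shows. RNA of crushed eyes mixed into it, or an exchange with a crushed eye, would raise all crush genes by 1 share: of the 26 genes higher after crush in a fit without this library, that share had a median of 38.9%, but 6 of them (Ndc80, Gm13889, Sox11, Avil, Crabp2 and Prss12) lay over 3 residual SD below the value it predicts, at or below the highest of the other controls. An earlier form of this test, which compared that share with the 52.8% of other gliosis genes, did not separate them (permutation p = 0.372) and was replaced by the count of genes. A larger share of Müller glia RNA would raise homeostatic and gliosis genes alike. In this library their medians were 0.22 and 0.83, a difference of -0.613 (permutation over genes, p = 4e-05). That permutation treats genes of 1 library as replicates, and the gliosis list was taken up because it stood high there. Its p does not measure the spread between libraries, so whether a larger share contributes cannot be told. A sham procedure in this fellow eye, or another irritation of the eye, stays open and untested, since the labels do not say which controls were sham-operated.

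In the crushed eyes ganglion cell markers were lower and microglia markers higher within a fraction meant to hold glial RNA. A changed share of all other cells in the fraction, acting alone, would move both the same way. The microglia minus ganglion cell median was 1.14 to 3.31 in ONC and -0.09 to 0.04 in Control, which argues against that share as the only cause. Its difference of 2.42 (exact permutation test over splits that ignore the pairs, p = 0.0159) was formed after both lists were seen, so the p adds no support. A changed share beside other changes stays open. The ganglion cell marker median fell by 0.812 (exact permutation test over splits that ignore the pairs, p = 0.00794, the smallest that 126 splits allow). That median measures the level of these markers, not the amount of ganglion cell RNA, and Gap43 of the same list was higher. More ganglion cell RNA would raise the markers only if their level per cell were unchanged, which was not tested. Whether such RNA accounts for the rise of Sox11 and Ecel1 therefore cannot be told. A lower share of all retinal neurons would lower rod, bipolar and amacrine markers as much as ganglion cell markers. Within pools the ganglion cell median fell beyond theirs in 4 of 4, by a mean of -0.607 ± 0.114 (SD). Without pool 914/92 that mean was -0.642 ± 0.111 (SD). However, 4 pairs cannot give an exact p under 0.125, and the unpaired difference of -0.486 did not pass (exact permutation test, p = 0.151). Cone and horizontal cell markers were left out of this comparison. Their median differences were -0.43 and -0.68, beside -0.82 for ganglion cell markers. The ganglion cell median minus that of rod, bipolar and amacrine markers ran from -0.88 to 0.11 in ONC and from -0.37 to 0.61 in Control. The groups overlap there, and the fall beyond those neurons shows within pools alone, where the pairs are too few to test it. A lower share of all retinal neurons therefore stays open. A changed retina sampled at a constant carry-over, carry-over of ganglion cell RNA and expression by Müller glia themselves all stay open. No unpurified fraction was analysed here.

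Y-linked RNA differs between the 2 libraries of pool 914/92 by -6.61, against at most 0.311 in size in the other pools. This fits libraries that do not hold the same animals, by a mix-up of numbers or of retinae, and the intermediate value of the control, -1.22, may come from retinae of both sexes. In the 6 libraries of the 3 pools with like Y-linked values the log2 differences of the 50 genes were 0.775 to 1.15 times those of all libraries (median 0.978), all 50 at an unadjusted p under 0.05, though limma called 0 genes there at an adjusted p under 0.05 and 2176 at an unadjusted p under 0.05. The 50 were called on these libraries too, so their sizes do not decide whether the Y-linked difference enters the calls. With the Y-linked level as a covariate limma called 0 genes at an adjusted p under 0.05. Almost no Y-linked RNA was seen in ONC 913/986 and ONC 914/92 (means -7.88 and -7.83) and in no Control library. The Y-linked difference is therefore partly confounded with crush. Over all genes, 22.7% showed no overlap of ONC and Control in these 6 libraries, against 10% by chance and at most 14.8% in the other splits of these 6, but 10 splits are too few for a share under 0.05.

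Other splits of the 9 libraries into 5 and 4 were drawn 100 times out of 126, the real one included. For changed genes, 3 splits gave as many as the real 50, and the highest of the others gave 2595. For higher genes, 3 gave as many as 27 (highest other 1412), and for lower genes 3 gave as many as 23 (highest other 1183). These counts are under 1 in 20 of all drawn splits, but most of those do not part the pairs. Chance is therefore not excluded for paired eyes. For gene lists the count was not under 1 in 20, since 7 splits gave as many as 23 lists (highest other 25). The other splits gave a median of 10 lists, so camera passed many lists without the real grouping. The split with 2595 genes sets Control 914/92, ONC 913/986, ONC 914/92 and ONC 976/978 against the rest, and a second with 577 genes sets 3 controls and ONC 981/982 against the rest, which points to a structure of the samples other than crush. Among the 14 drawn splits that part all 4 pairs, limma called genes in the real one alone. Only 16 such splits are possible, too few for a share under 1 in 20. The others gave 0 genes, at most 855 at an unadjusted p under 0.05 against 2788, and at most 19 lists (median 12).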

How the results depend on the processing

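Alternatives beyond those planned, named in the methods as added, were chosen after seeing the data. The calls are near the threshold: the 50 genes, whose groups do not overlap and so cannot change direction when libraries are left out, had 0.557 to 1.21 times their log2 differences over the settings, but did not keep their side of the threshold. By limma, 0 genes passed with the animal pool as a block (3574 at an unadjusted p under 0.05, and 919 at an adjusted p under 0.1), with quantile normalization (1848), without the 2 ONC libraries low in Y-linked RNA (1571), without the 3 libraries low in it (2176), with the block and without pool 914/92 (2630), with the Y-linked level as a covariate (1805) and over genes that passed the filter in both conditions (2672, for 40 of the 50). The block with a trend also called 0% of simulated changes, against 91.6% of those of 3 on the log2 scale with the block and no trend; for the other losses the cause was not tested. Counts were 29 with each library centred on its median (18 higher, 11 lower, so 62.1% higher in place of 54%), 165 without a trend (73 higher, 92 lower), 10 with robust weights (10 higher, 0 lower), 288 at an adjusted p under 0.1 (139 higher, 149 lower), 129 with the block and no trend, added after seeing the data (68 higher, 61 lower, with 27 of the 50), 71 with neuron markers as a covariate (24 higher, 47 lower), 44 without pool 914/92 (41 higher, 3 lower) and 36 with a log2 difference of at least 1 (24 higher, 12 lower). Leaving out 1 library gave 0 to 68 changed genes, 0 to 32 higher and 0 to 36 lower, with log2 differences of the 50 at 0.879 to 1.13 times the reported ones. The 23 lists became 0 with an estimated correlation (6 at an unadjusted p under 0.05), 22 with the block and 17 to 28 with 1 library left out, and 16 of the 23 passed in all 21 settings other than the estimated correlation. The rod list's direction turned, without passing, in 3 settings: without the 2 ONC libraries low in Y-linked RNA (adjusted p = 0.592), with the Y-linked level (0.596) and with neuron markers (0.328) as a covariate, of which the last holds the rod markers and so says nothing of their stability. Of 96 named genes no called one changed sign, and 10 uncalled ones did in some setting. The block changed no other call of a list or gene over all genes than those given. The filter on genes above the median level was not run, as the values hold no level, and other pseudocounts do not apply to log2 values. Depth is unknown and could not be weighed.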

Other observations

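The genes and the covariate fit given here were chosen after the results were seen. Several genes past the threshold belong to no list fixed beforehand and were picked out after their values were seen. Higher in ONC were the neuropeptides Crh (5.32-fold) and Adcyap1 (2.89-fold), Avil, an actin regulator of sensory neurons (9.53-fold), Hrk, a BH3-only activator of cell death (5.04-fold), Stmn4, a tubulin-binding protein of neurons (3.79-fold), the homeobox gene Hoxb9 (4.89-fold), Slpi, an inhibitor of leukocyte proteases (7.89-fold), and the integrin subunit Itga5 (1.89-fold). Lower were the potassium channel subunit Kcna2 (1.59-fold), the synaptic proteins Cplx1 (1.97-fold) and Syt10 (2.02-fold), Vsnl1, a neuronal calcium sensor (1.88-fold), and Fgf12, a regulator of sodium channels (2.02-fold). All passed limma's test at an adjusted p under 0.05, and each was changed the same way in 4 of 4 pools.

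Markers of cells other than Müller glia varied between libraries of 1 group. The mean of the rod, bipolar and amacrine medians was -0.52 in Control 914/92, -0.60 in ONC 913/986, -0.97 in ONC 914/92 and -0.50 in ONC 976/978, and lay between -0.06 and 0.13 in the other 5 libraries. The endothelial median was -0.95 in Control 914/92 and 0.87 in Control 981/982. The same 4 libraries form one side of the split of libraries that gave 2595 genes. With the neuron marker level as a covariate 71 genes changed, 33 of them among the 50, with log2 differences of the 50 at a median of 0.953 times the reported ones.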
